A study of Mus musculus with 24 samples.

How the data were processed

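RNA from primary mouse microglia was sequenced in 24 libraries: 2 genotypes, wild type (C57BL/6) and CD14-deficient (B6.129S4-Cd14tm1Frm/J), each untreated or stimulated for 3 h with 0.1 or 10 ng/ml Re-LPS or 100 µg/ml mouse fibronectin, with 3 libraries in each of the 8 groups. Libraries were made with a TruSeq kit and run on a HiSeq2000, per the labels' protocols. Reads were handled with CASAVA 1.8.2, FastQC 0.10.0, Bowtie2 2.1.0, SAMtools 0.1.19, HTSeq 0.5.4 and DESeq on the mm10 genome, per the submitters' processing notes, which state neither the annotation nor whether the strand was used. The deposited count table held whole read counts of 18919 gene symbols in every library. The deposited normalized table held a signal for 12889 of those genes, which equalled the counts divided by 1 factor per library to within 0.203 for KO FN replicate 3 and 0.0508 for the others.

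The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13294. Libraries were scaled by the trimmed mean of M-values (TMM). A quasi-likelihood model with robust dispersion estimates was fitted to the 8 groups in all 24 libraries, with 16 residual degrees of freedom, and 17 contrasts were tested. These were each stimulus against untreated cells in each genotype, KO against WT at each of the 4 treatments, the interaction of genotype with each of the 3 stimuli, LPS 10 against 0.1 ng/ml in each genotype, and FN against LPS 10 ng/ml in each genotype. The p-values were adjusted by Benjamini and Hochberg within each contrast and a gene was called at an adjusted p under 0.05. The contrasts of the report, the test, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Fold changes used a prior count of 0.125, and standard errors were the absolute log2 fold change divided by the square root of the F statistic. An interaction is the log2 fold change of a stimulus in KO cells minus that in WT cells. For a gene with 3 counts or fewer in a group, the ratio of the pooled counts over TMM-scaled library sizes is given with its counting interval, and no gene with a group at 0 is named.

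Genes were named by a fixed rule. Cd14, Tnf, Il6, Il12b, Cxcl1, Cxcl10, Ccl5 and Ifnb1 were named always. Others came from the 10 largest rises and the 10 largest falls among the genes called with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, and from each list up to 4 called members with the largest change and up to 2 uncalled members with the highest level. For contrasts with fewer than 10 calls all were named. A gene that the rule allows is not reported here because it is withheld.

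Gene lists were written from general knowledge. They covered cytokines, chemokines, interferon-stimulated genes, NF-kB pathway genes with feedback inhibitors, immediate early genes, the TLR4 receptor and its signalling, homeostatic microglia, phagocytosis and lysosome, MHC class I presentation, MHC class II and costimulation, nitric oxide with prostanoid and immunometabolism genes, cholesterol synthesis, cell cycle, matrix with integrins and proteases, heat shock and unfolded protein stress, mitochondrially encoded genes, astrocytes, oligodendrocyte lineage, neurons, vascular and fibroblast cells, other leukocytes, sex-linked genes and the neighbours of Cd14 on chromosome 18. Of these 23 lists, 21 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, with adjustment over 357 tests of list and contrast; mitochondrially encoded and other leukocyte genes had too few. Each list also has the number of members called when p-values were adjusted over the list alone.

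Libraries with the same replicate number were checked for shared deviations from their group means over 8450 genes. Within a genotype, libraries of the same number correlated at 0.557 to 0.952 and those of other numbers at -0.749 to 0.255, and all 24 libraries had their best partner under their own number. The labels describe independent preparations, so this pairing comes from the data. Between genotypes at the same treatment, same-numbered libraries correlated at 0.727 to 0.814 for number 1, 0.162 to 0.288 for number 2 and 0.0936 to 0.199 for number 3, the lowest value being that at LPS 10 ng/ml. Fits with the replicate number as a block over all libraries, and with a replicate block nested in the genotype (6 blocks), were alternatives. The main fit has no block and takes the 24 libraries as independent. Its residual degrees of freedom are therefore overstated for contrasts between the genotypes.

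Further alternatives were DESeq2 1.42.0, limma 3.58.1 with trend and robust options on log2 of the deposited normalized signal plus 1, RLE scaling, no filter, a filter of at least 5 CPM in 3 libraries, fits of the compared groups alone, leaving out each library in turn, and camera with an estimated correlation, on RLE-scaled values and with a replicate block. Leaving Rn45s out, and leaving out the 3 libraries in which it exceeded 3% of the counts, were chosen after seeing the data.

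Library totals were 14939019 to 22143774 counts. Pairs of replicate libraries differed more than counting error alone, with a chi-squared per degree of freedom from 36.8 to 224 where counting error alone gives 1. The tests were tried on simulated data in which 200 of 13294 genes were changed. In a contrast of 2 WT groups, edgeR called 56% of 2-fold and 88% of 4-fold changes with 9 false calls. In a contrast of 2 KO groups it called 55% and 92% with 3 false calls, and in an interaction 15% and 81% with 7. The simulated libraries were drawn independently, without deviations shared by replicate number, and few genes were changed. These shares therefore need not hold in the real contrasts. Gene positions and exon overlaps came from GENCODE vM21 (GRCm38/mm10), in which 313 of 321 genes named by the rule were found by symbol. Where a named gene shares over 10% of its exon length with another gene, the counts of both are uncertain and this is stated with its value.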

Results

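RNA sequencing measured gene expression in primary microglia, the resident macrophages of the mouse brain, in 24 libraries. The cells came from wild-type C57BL/6 mice (WT) or from mice without CD14 (KO), the surface co-receptor that passes lipopolysaccharide (LPS) to the TLR4 complex. In each genotype, cultures were left untreated or received 1 of 3 stimuli for 3 h. These were Re-LPS, a truncated LPS without O-antigen, at 0.1 or 10 ng/ml, and mouse fibronectin (FN), a glycoprotein of plasma and matrix, at 100 µg/ml. Each of the 8 groups held 3 libraries, which the series describes as independent cell preparations. Total counts per library ran from 14939019 in KO FN replicate 3 to 22143774 in WT FN replicate 1, and 13294 of 18919 listed genes passed a filter on low counts. Levels are CPM, the counts over library sizes scaled by the trimmed mean of M-values (TMM) and set to a common sum (mean ± SD, n = 3), and changes are log2 fold changes ± standard error between groups of 3 libraries. Adjusted p-values of genes came from edgeR quasi-likelihood tests with Benjamini-Hochberg (BH) adjustment, and those of gene lists from camera. Except where stated, the 3 libraries of the higher group all lay above the 3 of the lower group for each gene said to have risen or fallen, a separation that chance gives for 10% of genes.

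The libraries differed in RNA composition. TMM factors, which scale for it, were 1.18 to 1.30 in untreated WT libraries. They were 0.668 to 0.770 in WT cells at LPS 10 ng/ml and 0.648 to 0.773 with FN. In KO cells they were 1.20 to 1.35 untreated and 1.07 to 1.22 with FN. These factors enter every level and fold change. TMM scaling takes most genes as unchanged, yet 49.4% of tested genes were called in WT cells at LPS 10 ng/ml and 50.2% with FN. Whether more genes rose or fell there depends on the scaling. Rn45s, a ribosomal RNA precursor, took 3.62% of the counts in WT LPS 0.1 ng/ml replicate 3 (95% Wilson interval 3.61 to 3.63), 5.92% in WT LPS 10 ng/ml replicate 3 (5.91 to 5.94) and 8.21% in KO LPS 0.1 ng/ml replicate 2 (8.20 to 8.22). The other 21 ran from 0.0342% (0.0333 to 0.0351) in KO FN replicate 3 to 0.785% (0.780 to 0.789) in WT untreated replicate 3. These intervals cover counting error only. The first principal component of log2 CPM held 67.6% of the variance and the second 13.2%.

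Cd14, the gene removed in the KO mice, lies on chromosome 18 from 36725067 to 36726798 on the minus strand (GRCm38/mm10). Its level in the 3 untreated WT libraries was 1150, 639 and 338 CPM. It ran from 935 to 3120 CPM in WT libraries at LPS 0.1 ng/ml, from 2349 to 5329 CPM at LPS 10 ng/ml and from 2177 to 5089 CPM with FN. All 12 KO libraries held 2.14 to 6.37 CPM. Between untreated cultures Cd14 was lower in KO cells by a log2 fold change of -7.49 ± 0.62 (adjusted p = 5.4e-06), a call that was lost in a fit of those 6 libraries alone (adjusted p = 0.142). In WT cells it rose with LPS 10 ng/ml (2.43 ± 0.49, adjusted p = 3.8e-04) and with FN (2.41 ± 0.49, adjusted p = 3.9e-04). The rise with LPS 0.1 ng/ml (1.56 ± 0.47, adjusted p = 0.0299) separated 2 of 3 libraries from all untreated ones, and the call ended without WT untreated replicate 2 (adjusted p = 0.0997) or 3 (0.144) and without WT LPS 0.1 ng/ml replicate 1 (0.186) or 2 (0.0737), as it did in a fit of those 6 libraries alone (0.167).

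Untreated KO and WT cultures were compared for differences that precede any stimulus. Cd14 was the only gene called by edgeR among 13294, with 130 genes at an unadjusted p under 0.05. DESeq2 called 2 genes and limma on the normalized values 1. With the replicate number as a block, 19 genes passed, of which 3 were higher and 16 lower in KO cells. Tnf had a log2 fold change of -0.18 ± 0.43 and Cxcl10, an interferon-inducible chemokine, one of 0.20 ± 0.52, both uncalled. No member of the lists of cytokines (19 tested), chemokines (19), interferon-stimulated genes (36) or homeostatic microglial genes (18) was called, over all genes or adjusted over the list alone. The homeostatic list had a median of -0.16 (camera adjusted p = 0.0415, adjusted p = 0.112 with an estimated correlation, and 0.0547 with the replicate number as a block). Lists of markers of other brain cells were compared as well. The oligodendrocyte lineage list had a median of -1.57 over 12 genes (camera adjusted p = 1.1e-07, and adjusted p = 0.174 with an estimated correlation), with Mbp at 105 ± 34.8 CPM in WT and 83.1 ± 9.35 CPM in KO. The astrocyte list had a median of -0.74 over 12 genes (camera adjusted p = 0.00751, and adjusted p = 0.501 with an estimated correlation), and 0 genes of either list were called. The CPM of the astrocyte genes summed to 26.3, 63.5 and 64.1 in the WT libraries and 25.3, 89.5 and 47.4 in the KO libraries. Those of the oligodendrocyte lineage genes summed to 247.9, 434.6 and 224.6 in WT and 230.7, 246.4 and 184.3 in KO, which overlap. The neuron list had a median of 0.40 (camera adjusted p = 0.966). Of 5 sex-linked genes none was called, while camera called the list upward (median 0.73, camera adjusted p = 1.1e-04, and adjusted p = 0.0479 with an estimated correlation). Its members went in opposite directions, Xist, expressed from the inactive X chromosome, at -0.82 ± 0.57 and the Y-linked Ddx3y at 0.71 ± 0.37. Camera also called NF-kB genes (median -0.26, adjusted p = 4.8e-06, and adjusted p = 0.429 with an estimated correlation), cell cycle genes (-0.32, 1.4e-05, and adjusted p = 0.520 with an estimated correlation) and cholesterol synthesis genes (0.16, 3.6e-04, and adjusted p = 0.426 with an estimated correlation), with 0 calls in each. The CPM of the cell cycle genes summed to 1933, 1354 and 1614 in the WT libraries and 2309, 1161 and 534 in the KO libraries, of which replicate 3 stayed lowest at every treatment (397 to 534). The 42 tested neighbours of Cd14 on chromosome 18 had a median of 0.01 (camera adjusted p = 0.815).

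The lower LPS dose was compared with untreated WT cells. Interferon-inducible genes were among its largest rises. Cxcl10 rose from 12.9 ± 4.95 to 3080 ± 1226 CPM (log2 fold change 7.89 ± 0.70, adjusted p = 2.7e-07), and the antiviral effectors Rsad2 (6.80 ± 0.57) and Ifit1 (6.67 ± 0.57) and the guanylate-binding protein gene Gbp5 (6.77 ± 0.52) rose with it. Ifnb1, which encodes interferon beta, held 3 counts in the untreated WT libraries together and 275 at this dose, a ratio of 104 with a 95% counting interval from 35.3 to 509, from pooled counts over the same scaled library sizes. Tnf rose by 5.66 ± 0.52 and Il6, a secreted pro-inflammatory cytokine, by 5.70 ± 0.70. Il12b, the p40 subunit of IL-12 and IL-23, rose by 6.42 ± 0.71, the neutrophil-attracting chemokine Cxcl1 by 6.24 ± 0.79 and the T cell-attracting Ccl5 by 5.56 ± 0.65. Irg1, which makes itaconate, rose by 7.06 ± 0.72 and the early activation marker Cd69 by 7.43 ± 0.49. The largest falls with no overlap between libraries were in Thbd (-3.13 ± 0.53), the anticoagulant receptor thrombomodulin, the nucleotide and lipid receptor gene Lpar6 (-2.92 ± 0.32) and the glycosidase gene Engase (-2.88 ± 0.50).

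By list, 35 of 36 interferon-stimulated genes rose at LPS 0.1 ng/ml in WT cells (36 adjusted over the list alone), with a median of 3.78 (camera adjusted p = 1.6e-56). Of 27 NF-kB pathway genes and feedback inhibitors, 26 rose (27 adjusted over the list alone), among them Socs1 (6.47 ± 0.73), Traf1 (6.22 ± 0.62) and Socs3 (5.69 ± 0.50). The cytokine list rose in 14 of 19 genes (15 adjusted over the list alone) and the chemokine list in 16 of 19 (16 adjusted over the list alone), the latter with Cxcl3 (5.97 ± 1.28) and Cxcl2 (5.82 ± 0.97). The list of nitric oxide, prostanoid and immunometabolism genes rose in 14 of 20 (14 adjusted over the list alone), including Ptges (5.82 ± 0.49) and Ptgs2 (5.35 ± 0.53), which make prostaglandin E, and Nos2 (4.89 ± 0.62), the inducible nitric oxide synthase. Antigen presentation by MHC class I rose in 12 of 15 genes (13 adjusted over the list alone), with the peptide transporter Tap1 at 2.47 ± 0.26. Camera called these 6 lists with the preset correlation and with an estimated one (adjusted p from 0.0162 for NF-kB genes to 0.0439 for MHC class I). In all, 2075 genes were called, 1322 up and 753 down, and 5520 with a replicate block nested in genotype (2814 up and 2706 down). Without WT LPS 0.1 ng/ml replicate 1 the count was 1317. A fit of those 6 libraries alone called 1357 and ended the call of Cxcl3 (adjusted p = 0.0726).

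At LPS 10 ng/ml, WT cells reached far higher cytokine levels. Tnf rose from 26.2 ± 12.6 to 6648 ± 661 CPM (7.99 ± 0.57, adjusted p = 2.4e-09), Il6 from 0.430 ± 0.234 to 616 ± 139 CPM (10.46 ± 0.81, adjusted p = 5.6e-09) and Il12b to 2407 ± 613 CPM (10.21 ± 0.82). Cxcl10 reached 13360 ± 2180 CPM (10.01 ± 0.76), Ccl5 2133 ± 308 CPM (8.53 ± 0.74) and Cxcl1 154 ± 50.2 CPM (8.69 ± 0.85). Ifnb1 rose to 178 ± 41.1 CPM, 3624 times its untreated level by pooled counts, with a 95% counting interval from 1240 to 17580. Over library totals without TMM scaling the ratio was 2084 (712.7 to 10110). Among the largest falls with no overlap between libraries were the cannabinoid receptor gene Cnr2 (-6.20 ± 0.54), the chemokine receptor gene Cxcr4 (-6.11 ± 0.86), the pro-apoptotic Bmf (-5.97 ± 0.61), the myeloid transcription factor Cebpa (-5.51 ± 0.40) and the receptor gene Cd300lb (-6.26 ± 0.39). All 36 interferon-stimulated genes rose (36 adjusted over the list alone; camera adjusted p = 2.1e-28, and adjusted p = 0.0710 with an estimated correlation), as did all 27 NF-kB genes (27 adjusted over the list alone; camera adjusted p = 1.9e-37). The cytokine and chemokine lists each rose in 18 of 19 genes (18 adjusted over the list alone in each), with Ccl7 at 9.80 ± 0.62 and Cxcl11 at 9.19 ± 0.75. GENCODE lists Cxcl11 as a polymorphic pseudogene, so whether its transcript yields a chemokine is not known here. Nos2 rose by 9.35 ± 0.71 and Ptgs2 by 9.30 ± 0.62. Of 18 homeostatic microglial genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.180), with the fractalkine receptor gene Cx3cr1 at -2.56 ± 0.22 and Gpr84, a medium-chain fatty acid receptor gene that rose, at 4.94 ± 0.55. The fit called 6570 genes, 3097 up and 3473 down.

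The doses were compared directly in WT cells. Between LPS 0.1 and 10 ng/ml, 4285 genes changed, 1968 higher and 2317 lower at the higher dose, and 7576 with the nested replicate block. Il6 was higher by 4.76 ± 0.60, Il12b by 3.79 ± 0.61, Tnf by 2.32 ± 0.44 and Nos2 by 4.46 ± 0.55. Cxcl10 differed less (2.12 ± 0.53), and without the 3 libraries rich in Rn45s, a setting chosen after seeing the data, its call ended (adjusted p = 0.0763). Of 36 interferon-stimulated genes 24 were higher (28 adjusted over the list alone; camera adjusted p = 1.6e-14, and adjusted p = 0.223 with an estimated correlation), and of 27 NF-kB genes 24 (25 adjusted over the list alone; camera adjusted p = 3.2e-22, and adjusted p = 0.0581 with an estimated correlation). Cd14 was not called (0.87 ± 0.47, adjusted p = 0.179) and was with the nested block (adjusted p = 6.1e-06). Without the 3 libraries rich in Rn45s, 2419 genes changed between the doses.

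FN was compared with untreated WT cells. It raised the genes raised by LPS 10 ng/ml, to like levels. Tnf reached 7475 ± 1539 CPM (8.15 ± 0.58, adjusted p = 2.0e-09), Il6 616 ± 114 CPM (10.46 ± 0.81), Il12b 2534 ± 795 CPM (10.29 ± 0.82), Cxcl1 175 ± 88.0 CPM (8.88 ± 0.85), Cxcl10 13800 ± 2891 CPM (10.06 ± 0.76) and Ccl5 2164 ± 560 CPM (8.55 ± 0.74). Ifnb1 reached 172 ± 23.6 CPM, 3488 times the untreated level by pooled counts, with a counting interval from 1193 to 16920. Over library totals without TMM scaling the ratio was 2011 (687.9 to 9754). Cnr2 (-6.67 ± 0.56), Bmf (-6.52 ± 0.63), Cxcr4 (-6.10 ± 0.85) and Cd300lb (-6.01 ± 0.39) fell again. All 36 interferon-stimulated genes, all 27 NF-kB genes and all 19 cytokines rose, over all genes and adjusted over the list alone, as did 18 of 19 chemokines (18 adjusted over the list alone). Camera called the 4 lists (adjusted p = 9.3e-28, 6.0e-37, 1.8e-15 and 6.9e-16); with an estimated correlation the interferon-stimulated list had adjusted p = 0.0729 and the chemokine list adjusted p = 0.0517. In all 6670 genes were called, 3153 up and 3517 down.

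Set directly against each other, WT cells with FN and with LPS 10 ng/ml differed in 0 genes by edgeR, by DESeq2 and by limma on the normalized values, with 105 genes at an unadjusted p under 0.05 in edgeR. The count stayed at 0 with either replicate block. Log2 differences were 0.17 ± 0.42 for Tnf, 0.07 ± 0.55 for Il12b, 0.05 ± 0.51 for Cxcl10, 0.19 ± 0.57 for Cxcl1, -0.04 ± 0.56 for Ifnb1 and -0.02 ± 0.46 for Cd14. Over the 6570 genes called at LPS 10 ng/ml, the median absolute log2 difference was 0.08 and the median 95% half-width of the difference was 0.43. No list was called by camera between these stimuli without a block (cytokines, adjusted p = 0.131), and with the nested block the cholesterol synthesis list was (median -0.08, adjusted p = 0.170 without and 0.0170 with the block).

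**Figure D1:**
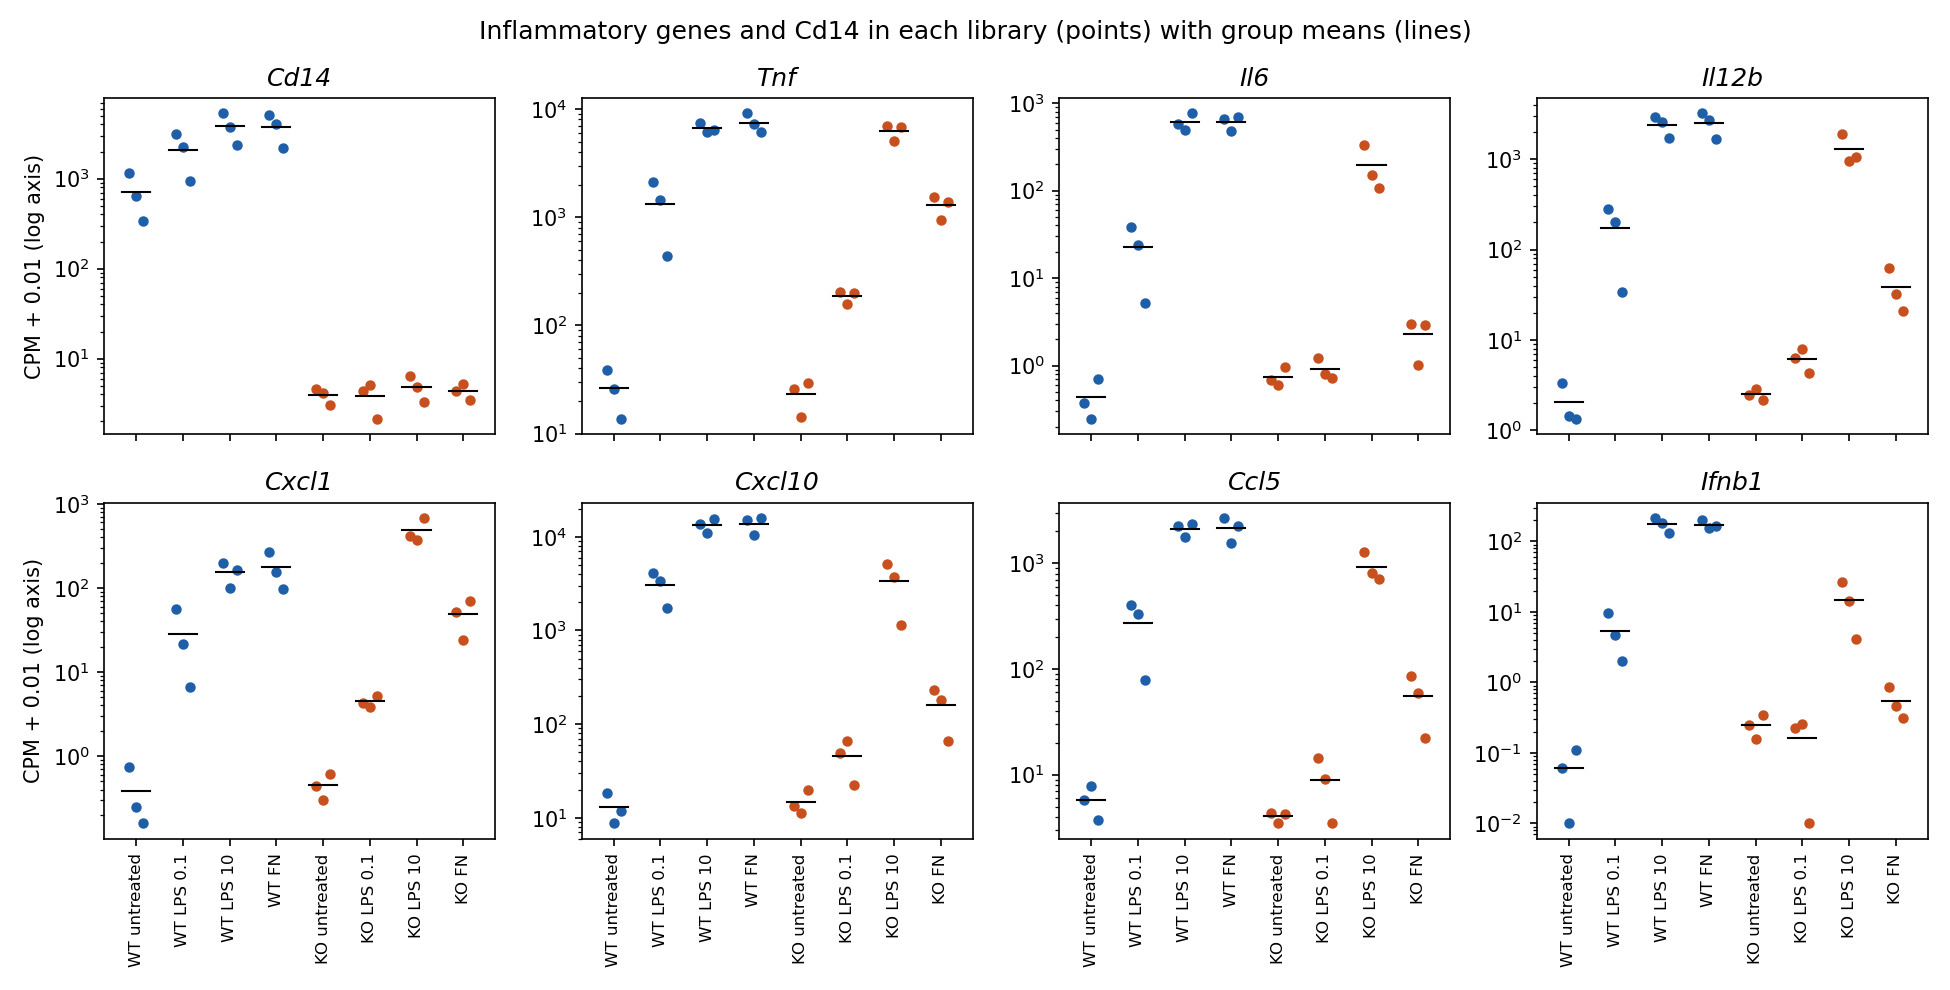
CPM plus 0.01 on a log axis for Cd14 and 7 inflammatory genes in each library (points; blue wild type, orange CD14-deficient; lines are group means, n = 3). In wild-type cells the LPS 10 ng/ml and FN groups sit at like levels in every panel, while in CD14-deficient cells the FN group lies below the LPS 10 ng/ml group for the 7 inflammatory genes.

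Without CD14, the lower LPS dose left a small response that held NF-kB genes. Tnf rose from 23.1 ± 7.91 to 187 ± 26.1 CPM (3.02 ± 0.46, adjusted p = 0.00127). Nfkbie, an NF-kB inhibitor, rose by 3.00 ± 0.30 (adjusted p = 1.5e-05), the lipopeptide receptor gene Tlr2 by 2.81 ± 0.30, Gpr84 by 3.19 ± 0.51, Cd69 by 3.02 ± 0.41, Socs3, a feedback inhibitor of cytokine signalling, by 2.80 ± 0.44, Ptges by 2.77 ± 0.45 and Cdc42ep2, which binds a small GTPase of the cytoskeleton, by 3.46 ± 0.41. Of 27 NF-kB genes 17 rose (25 adjusted over the list alone), with a median of 1.73 (camera adjusted p = 3.0e-146, and adjusted p = 5.0e-04 with an estimated correlation). None of 36 interferon-stimulated genes was called by edgeR without a block, over all genes or adjusted over the list alone. Their summed CPM was 695.5, 1163.6 and 754.1 in the untreated KO libraries and 1053.1, 1623.4 and 779 at this dose. The sum was thus higher within each replicate number, so a small rise is not excluded. The interferon-stimulated list had a median of 0.38 (camera adjusted p = 6.2e-06, and adjusted p = 0.509 with an estimated correlation). Cxcl10 stood at 45.7 ± 21.8 CPM (1.62 ± 0.53, adjusted p = 0.358), and Il6, Il12b, Ccl5 and Ifnb1 were not called either. Cytokines rose in 2 of 19 genes (4 adjusted over the list alone; camera adjusted p = 1.5e-11, and adjusted p = 0.0633 with an estimated correlation), Tnf and Il1b (2.66 ± 0.44). Cxcl1 (3.34 ± 0.74, adjusted p = 0.0387) was 1 of 2 chemokines called of 19 (7 adjusted over the list alone; camera adjusted p = 5.0e-17). The Cxcl1 call ended without KO untreated replicate 1 (0.169), 2 (0.281) or 3 (0.106) and without KO LPS 0.1 ng/ml replicate 1 (0.0909), 2 (0.0749) or 3 (0.0972), and with limma (0.177) and without a filter (0.0653). In all 97 genes were called, 96 up and 1 down, with 577 at an unadjusted p under 0.05. The nested block called 515 (409 up and 106 down), and without KO untreated replicate 2 the count was 55. A fit of those 6 libraries alone called 45 and ended the call of Gpr84 (adjusted p = 0.102).

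The genotypes were compared at LPS 0.1 ng/ml to ask how far this dose acts through CD14. KO cells had less Cxcl10 (-6.07 ± 0.64, adjusted p = 8.3e-06), Rsad2 (-6.16 ± 0.55), Ifit1 (-5.82 ± 0.55) and Socs1 (-6.03 ± 0.70), less Il6 (-4.63 ± 0.64), Il12b (-4.82 ± 0.65), Ccl5 (-4.91 ± 0.63) and Tnf (-2.83 ± 0.45), and more Lpar6 (2.38 ± 0.31), Thbd (2.57 ± 0.52) and Gpr183 (2.099 ± 0.32), an oxysterol receptor gene. The interferon-stimulated list was lower in 33 of 36 genes (36 adjusted over the list alone; camera adjusted p = 1.9e-71) and the NF-kB list in 23 of 27 (23 adjusted over the list alone; camera adjusted p = 5.7e-32). In a fit of those 6 libraries alone, 179 genes were called, and Il6, Il12b, Ccl5, Tnf, Lpar6, Thbd and Gpr183 were not (adjusted p from 0.0564 to 0.111). The fit of all libraries called 1237 genes, 395 higher and 842 lower in KO cells, and 2507 with the replicate number as a block (1062 higher and 1445 lower). Without a block that fit takes libraries of the same number as independent, though they deviate together. Its calls between genotypes, here and at the other treatments, may therefore be too many. The count was 604 without WT LPS 0.1 ng/ml replicate 1, 648 without replicate 2, 1934 without replicate 3 and 782 without KO LPS 0.1 ng/ml replicate 3.

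The interaction tests whether the response itself differed between the genotypes. At LPS 0.1 ng/ml it called 305 genes, 280 of them with a weaker rise or stronger fall in KO cells and 25 the other way, and 1779 with the nested block (1015 and 764). It was negative for Cxcl10 (-6.28 ± 0.79, adjusted p = 2.4e-04), Rsad2 (-6.29 ± 0.68), Ifit1 (-5.94 ± 0.69), Il12b (-5.12 ± 0.87), Il6 (-5.38 ± 0.98, adjusted p = 0.00405) and Ccl5 (-4.39 ± 0.81). The interferon-stimulated list was weaker in 27 of 36 genes (35 adjusted over the list alone), with a median of -3.58 (camera adjusted p = 4.3e-99, and adjusted p = 0.00958 with an estimated correlation). The NF-kB list was weaker in 11 of 27 (20 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 2.1e-28, and adjusted p = 0.0412 with an estimated correlation). Cytokines were weaker in 8 of 19 genes (9 adjusted over the list alone; camera adjusted p = 2.6e-20) and chemokines in 10 of 19 (12 adjusted over the list alone; camera adjusted p = 9.5e-33). Tnf was called (-2.65 ± 0.61, adjusted p = 0.0240), but not without WT untreated replicate 2 (0.0638) or 3 (0.0685), WT LPS 0.1 ng/ml replicate 1 (0.101) or 2 (0.0560), KO untreated replicate 1 (0.0561) or 3 (0.0652), or KO LPS 0.1 ng/ml replicate 2 (0.0679) or 3 (0.0556), or in a fit of the compared groups alone (0.157). The interaction of Cd14 was not called (-1.59 ± 0.68, adjusted p = 0.386) and was with the nested block (adjusted p = 1.5e-04). The count was 180 without WT LPS 0.1 ng/ml replicate 1, 195 without replicate 2 and 624 without replicate 3.

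At LPS 10 ng/ml, KO cells raised the inflammatory genes strongly. Tnf reached 6276 ± 1074 CPM (8.08 ± 0.58, adjusted p = 4.7e-09), Il6 198 ± 121 CPM (8.08 ± 0.73), Il12b 1298 ± 508 CPM (9.02 ± 0.78), Cxcl1 487 ± 166 CPM (10.11 ± 0.88), Cxcl10 3353 ± 2038 CPM (7.82 ± 0.69), Ccl5 932 ± 307 CPM (7.86 ± 0.72) and Ifnb1 14.96 ± 11.2 CPM (5.97 ± 0.77). Cnr2 (-5.97 ± 0.53), Cxcr4 (-5.52 ± 0.82) and Thbd (-5.14 ± 0.59) fell. The NF-kB list rose in all 27 genes (27 adjusted over the list alone; camera adjusted p = 2.4e-47), the cytokine and chemokine lists in 18 of 19 each (18 adjusted over the list alone in each), and the interferon-stimulated list in 34 of 36 (35 adjusted over the list alone), with a median of 3.75 (camera adjusted p = 2.0e-22, and adjusted p = 0.118 with an estimated correlation). In all 5697 genes were called, 2819 up and 2878 down, and 8778 with the nested block. Between the doses 4883 genes changed in KO cells, 2430 higher and 2453 lower at 10 ng/ml, 8346 with the nested block and 3188 in a fit of those 6 libraries alone; Il6 was higher by 7.76 ± 0.72, Cxcl10 by 6.20 ± 0.64 and Tnf by 5.07 ± 0.50.

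Compared at LPS 10 ng/ml, the genotypes did not differ detectably in Tnf (-0.08 ± 0.42, adjusted p = 0.966) and differed in interferon-linked genes. KO cells had less Ifnb1 (-3.57 ± 0.63, adjusted p = 6.3e-04) and less of the polymorphic pseudogene Cxcl11 (-3.93 ± 0.57). Less was found too of Gbp4 (-3.95 ± 0.68), Cmpk2 (-3.25 ± 0.45) and the complement inhibitor gene Serping1 (-4.31 ± 0.73) in KO cells. KO cells had more Osgin1 (2.73 ± 0.34), which responds to oxidative stress, and Cd300lb (2.49 ± 0.34). Higher too were Lyl1 (2.38 ± 0.28) and Cebpa (2.36 ± 0.35), 2 transcription factors of blood cells, the microglial marker Tmem119 (1.97 ± 0.45) and Cx3cr1 (0.92 ± 0.21). The interferon-stimulated list was lower in 24 of 36 genes (31 adjusted over the list alone), with a median of -1.85 (camera adjusted p = 1.2e-25, and adjusted p = 0.0742 with an estimated correlation). The NF-kB list was lower in 4 and higher in 1 of 27 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00674, and adjusted p = 0.707 with an estimated correlation). Cxcl10 was lower (-1.995 ± 0.53, adjusted p = 0.0143), a call that ended without KO LPS 10 ng/ml replicate 3 (adjusted p = 0.0689). Il6 was lower (-1.64 ± 0.53, adjusted p = 0.0418), a call that ended without WT LPS 10 ng/ml replicate 1 (0.0729), 2 (0.0579) or 3 (0.118) and without KO LPS 10 ng/ml replicate 2 (0.144) or 3 (0.191). Il12b (-0.89 ± 0.55), Cxcl1 (1.66 ± 0.58) and Ccl5 (-1.19 ± 0.54) were not called by edgeR without a block. Cxcl1, higher in KO cells, was called by DESeq2 (adjusted p = 0.0274), by limma (0.0404), with the stricter filter (0.0469) and in a fit of those 6 libraries alone (0.0444). That fit ended the calls of Cxcl10 (adjusted p = 0.0928), Il6 (0.0952, and 0.0691 without a filter) and Gbp4 (0.0535), and called 645 genes, 198 higher and 447 lower. The fit called 2114 genes, 1070 higher and 1044 lower in KO cells, and 1300 without KO LPS 10 ng/ml replicate 3, where 572 were higher and 728 lower.

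The interaction at LPS 10 ng/ml called 702 genes, 441 negative and 261 positive, and 2887 with the nested block (1380 and 1507). Irf8, a transcription factor of the interferon regulatory family, gave the smallest adjusted p among the genes named. It went from 311 ± 20.6 to 1857 ± 305 CPM in WT cells and from 336 ± 8.41 to 129.4 ± 19.4 CPM in KO cells (interaction -3.95 ± 0.21, adjusted p = 3.1e-09). Ifnb1 (-5.65 ± 1.29, resting on the same 3 counts in untreated WT cells, adjusted p = 0.0135), Cxcl11 (-5.00 ± 0.88) and Gbp4 (-4.43 ± 1.03) had negative interactions. Osgin1 (2.47 ± 0.45), Cd300lb (2.45 ± 0.46), Lyl1 (2.26 ± 0.38) and Trib1 (2.16 ± 0.34), a pseudokinase gene, had positive ones. The interferon-stimulated list was weaker in KO cells in 9 of 36 genes (23 adjusted over the list alone), with a median of -1.90 (camera adjusted p = 5.1e-28, and adjusted p = 0.0677 with an estimated correlation). The NF-kB list was weaker in 2 and stronger in 1 of 27 genes (2 and 1 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.295). MHC class I presentation was weaker in 6 of 15 genes (8 adjusted over the list alone; camera adjusted p = 2.0e-09, and adjusted p = 0.0729 with an estimated correlation), with its transactivator Nlrc5 at -2.53 ± 0.55. Interactions of Tnf (0.10 ± 0.60), Il6 (-2.38 ± 0.92) and Il12b (-1.19 ± 0.83) were not called by edgeR, and DESeq2 called that of Il6 (adjusted p = 0.0400). Those of Cxcl10 (-2.20 ± 0.74, adjusted p = 0.107) and Cd14 (-2.13 ± 0.69, adjusted p = 0.0867) were not called by edgeR without a block and were with the nested block (adjusted p = 0.0141 and 2.5e-06) and by DESeq2 (0.0211 and 0.0173). The Cd14 interaction also passed with limma (adjusted p = 0.0416), without the 3 libraries rich in Rn45s (0.0396) and without WT untreated replicate 1 (0.0392). Without KO LPS 10 ng/ml replicate 3 the count was 445. A fit of the compared groups alone called 432 genes (291 negative and 141 positive) and ended the calls of Gbp4 (adjusted p = 0.0555) and Nlrc5 (0.0520).

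Fibronectin in KO cells raised NF-kB genes and chemokines and left most interferon-stimulated genes uncalled. Among the largest rises with no overlap between libraries were Cxcl2 (6.84 ± 1.02, adjusted p = 1.0e-04) and Cxcl1 (6.79 ± 0.79). Irg1 (6.62 ± 0.71), Ptges (6.56 ± 0.51), Traf1 (5.97 ± 0.63) and Olr1 (5.93 ± 0.66), a scavenger receptor gene, rose too. Tnf reached 1286 ± 310 CPM (5.80 ± 0.52, adjusted p = 3.1e-07), Cxcl10 160 ± 85.3 CPM (3.42 ± 0.57), Ccl5 55.5 ± 31.7 CPM (3.79 ± 0.60) and Il12b 38.8 ± 21.9 CPM (3.96 ± 0.63). Il6 stood at 2.29 ± 1.11 CPM (1.64 ± 0.65, adjusted p = 0.0992) and Ifnb1 at 0.528 ± 0.278 CPM (1.17 ± 0.82), both uncalled by edgeR. Il6 was called by DESeq2 (adjusted p = 0.0286) and without the 3 libraries rich in Rn45s (0.0365). The ubiquitin ligase gene Rnf144b (-4.59 ± 0.60) and Lpar6 (-3.58 ± 0.33) fell. Of 27 NF-kB genes 25 rose (25 adjusted over the list alone; camera adjusted p = 2.0e-74). Of 36 interferon-stimulated genes 5 rose (5 adjusted over the list alone), among them Gbp5 (3.65 ± 0.45), Gbp2 (2.80 ± 0.46) and Gbp3 (2.14 ± 0.47), with a list median of 0.54 (camera adjusted p = 0.00155, and adjusted p = 0.711 with an estimated correlation). Cytokines rose in 13 of 19 genes (14 adjusted over the list alone; camera adjusted p = 6.6e-13, and adjusted p = 0.0521 with an estimated correlation) and chemokines in 14 of 19 (16 adjusted over the list alone; camera adjusted p = 4.9e-17). In all 2180 genes were called, 1227 up and 953 down, and 5851 with the nested block (2860 up and 2991 down). A fit of those 6 libraries alone called 1246 (688 up and 558 down).

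Between the genotypes under FN, KO cells had less Il6 (-8.08 ± 0.71, adjusted p = 8.1e-08), Ifnb1 (-8.33 ± 0.80), Rsad2 (-8.24 ± 0.61), Cxcl11 (-8.46 ± 0.72), Cxcl10 (-6.43 ± 0.65), Il12b (-6.03 ± 0.68), Ccl5 (-5.29 ± 0.64) and Tnf (-2.54 ± 0.45), and more Bmf (5.62 ± 0.61), Cd300lb (5.20 ± 0.37), Lyl1 (4.04 ± 0.29) and the stress-response gene Sesn1 (3.91 ± 0.31). All 36 interferon-stimulated genes were lower, over all genes and adjusted over the list alone (median -5.39, camera adjusted p = 9.9e-40), as were 25 of 27 NF-kB genes (25 adjusted over the list alone; camera adjusted p = 7.2e-16, and adjusted p = 0.122 with an estimated correlation). Cxcl1 was lower (-1.85 ± 0.59, adjusted p = 0.0181), a call that ended without WT FN replicate 1 (0.0958) or KO FN replicate 2 (0.0855). The fit called 5130 genes, 2795 higher and 2335 lower in KO cells.

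The interaction for FN called 3069 genes, 1505 negative and 1564 positive, and 6553 with the nested block (3085 and 3468). It was negative for Ifnb1 (-10.41 ± 1.35, resting on 3 counts in the untreated WT libraries, adjusted p = 2.0e-05), Il6 (-8.83 ± 0.98, adjusted p = 4.5e-06), Rsad2 (-8.36 ± 0.72), Cxcl10 (-6.63 ± 0.80), Il12b (-6.33 ± 0.88), Ccl5 (-4.76 ± 0.81) and Tnf (-2.36 ± 0.61, adjusted p = 0.00807) and positive for Bmf (5.45 ± 0.75), Cd300lb (5.16 ± 0.47), Osgin1 (4.11 ± 0.46) and Sesn1 (4.11 ± 0.41). The Cxcl1 interaction was not called (-2.09 ± 1.07, adjusted p = 0.190). All 36 interferon-stimulated genes were weaker in KO cells, over all genes and adjusted over the list alone (median -5.31, camera adjusted p = 9.8e-54, and adjusted p = 0.0311 with an estimated correlation). The NF-kB list was weaker in 18 of 27 genes (19 adjusted over the list alone), with a median of -1.46 (camera adjusted p = 1.7e-13, and adjusted p = 0.159 with an estimated correlation). MHC class I presentation was weaker in 12 of 15 (13 adjusted over the list alone; camera adjusted p = 6.0e-16), cytokines in 14 of 19 (16 adjusted over the list alone; camera adjusted p = 1.1e-14) and chemokines in 12 of 19 (13 adjusted over the list alone; camera adjusted p = 1.7e-15, and adjusted p = 0.0502 with an estimated correlation). The Cd14 interaction (-2.26 ± 0.69, adjusted p = 0.0219) was not called without WT untreated replicate 3 (0.0538), WT FN replicate 1 (0.0603) or KO FN replicate 3 (0.0534).

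FN and LPS 10 ng/ml were set against each other in KO cells too. Against LPS 10 ng/ml, FN gave less Il6 (-6.45 ± 0.67, adjusted p = 8.8e-06), Il12b (-5.06 ± 0.65), Ifnb1 (-4.80 ± 0.71), Cxcl10 (-4.39 ± 0.59), Ccl5 (-4.07 ± 0.60), Cxcl1 (-3.33 ± 0.62) and Tnf (-2.29 ± 0.44), and less of the chemokine gene Ccl22 (-5.61 ± 0.67) and the cytokine gene Lif (-5.43 ± 0.69), and more Cd300lb (2.96 ± 0.33) and Fos (2.64 ± 0.37), an immediate early transcription factor. The interferon-stimulated list was lower in 34 of 36 genes (36 adjusted over the list alone; median -3.32, camera adjusted p = 1.8e-51) and the NF-kB list in 23 of 27 (24 adjusted over the list alone; median -1.30, camera adjusted p = 1.5e-25, and adjusted p = 0.0502 with an estimated correlation). The fit called 2258 genes, 1004 higher and 1254 lower with FN, 5952 with the nested block, and 879 (260 higher and 619 lower) in a fit of those 6 libraries alone. The count was 1498 without KO LPS 10 ng/ml replicate 1 and 1490 without KO FN replicate 2. Whether this contrast differed between the genotypes was not tested.

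**Figure D2:**
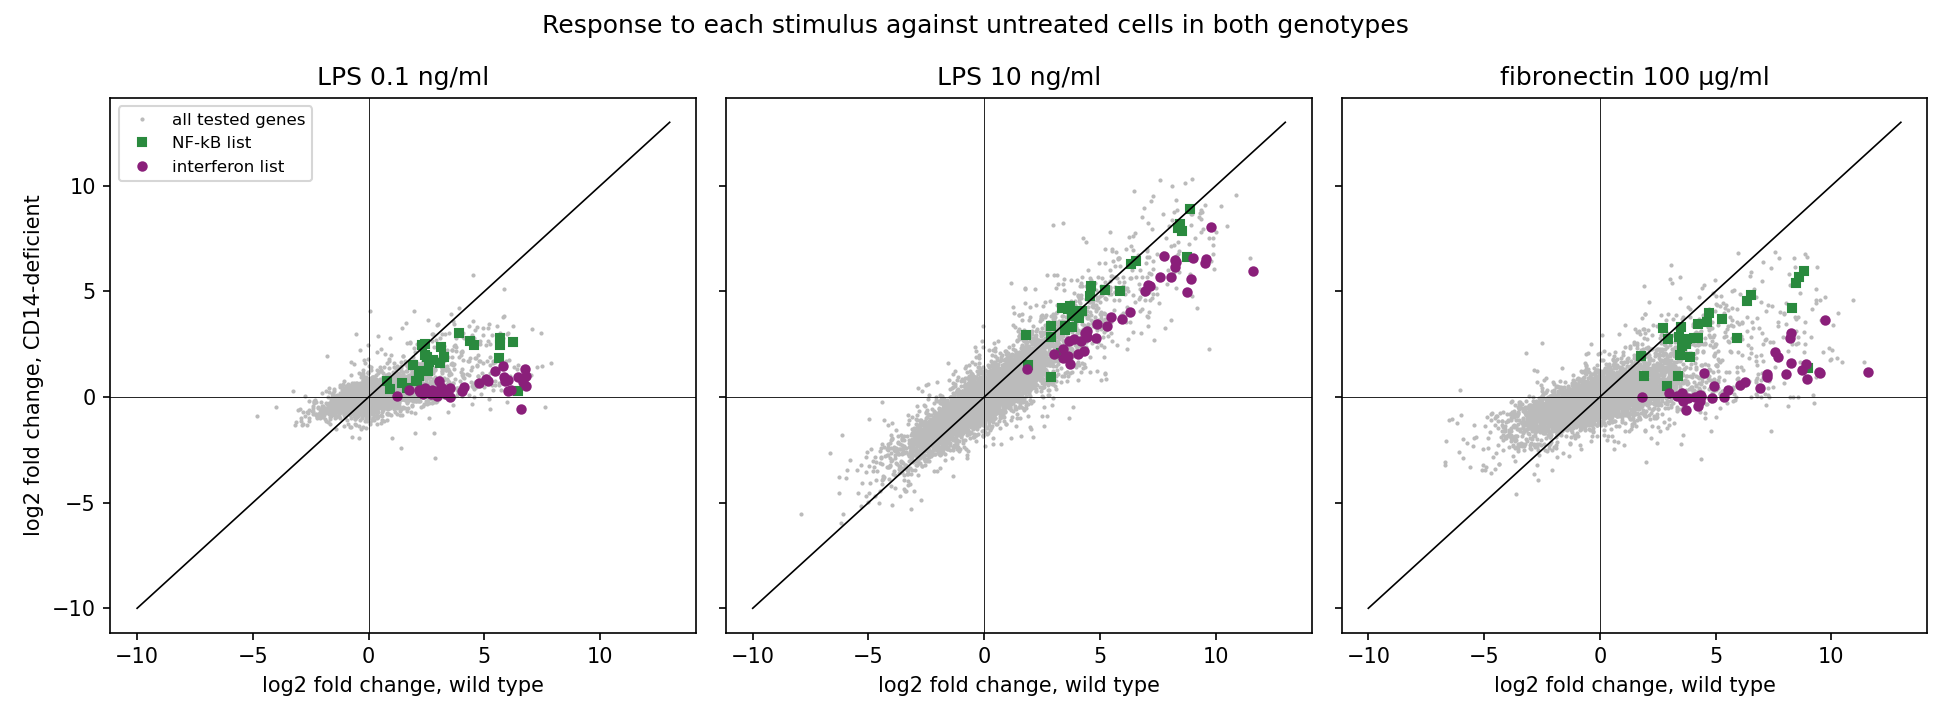
Log2 fold change against untreated cells in CD14-deficient cells (vertical axis) and in wild-type cells (horizontal axis) for the 3 stimuli; grey points are all tested genes, green squares the 27 NF-kB genes, purple circles the 36 interferon-stimulated genes, and the line marks equal responses. At LPS 0.1 ng/ml and with FN the medians of the interferon-stimulated genes in CD14-deficient cells are 0.38 and 0.54, close to the horizontal axis. Some members, among them Gbp5, Gbp2 and Gbp3, lie well above it with FN.

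To measure how much of the WT response stayed without CD14, genes with a called rise of at least 2-fold in WT cells at one stimulus were followed at another. The choice and the WT medians share the untreated WT libraries, which favours WT. Of 1820 genes picked at LPS 10 ng/ml, the median log2 fold change at LPS 0.1 ng/ml was 1.01 in WT cells (quartiles 0.55 and 1.96) and 0.21 in KO cells (0.04 and 0.54), and the interaction was negative for 276 and positive for 0. Of 767 genes picked at LPS 0.1 ng/ml, the median at LPS 10 ng/ml was 3.32 in WT cells (2.42 and 5.06) and 2.85 in KO cells (1.94 and 4.48), with 112 negative and 15 positive interactions. With FN the same 767 genes had medians of 3.31 in WT cells (2.42 and 5.01) and 1.39 in KO cells (0.57 and 2.42), with 488 negative and 12 positive interactions. FN and LPS 10 ng/ml raised 2992 genes in common and lowered 3246 in WT cells, against 735 and 919 for independent lists, with 0 called in opposite directions. In KO cells they raised 1180 in common and lowered 908, against 260 and 206, with 4 called in opposite directions. Both comparisons in a genotype share the same 3 untreated libraries, which cannot be split. Simulated unchanged groups against those controls shared 0 calls in 20 simulations. Groups without change are seldom called at all, so this cannot show how much the shared libraries add where many genes change.

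**Figure D3:**
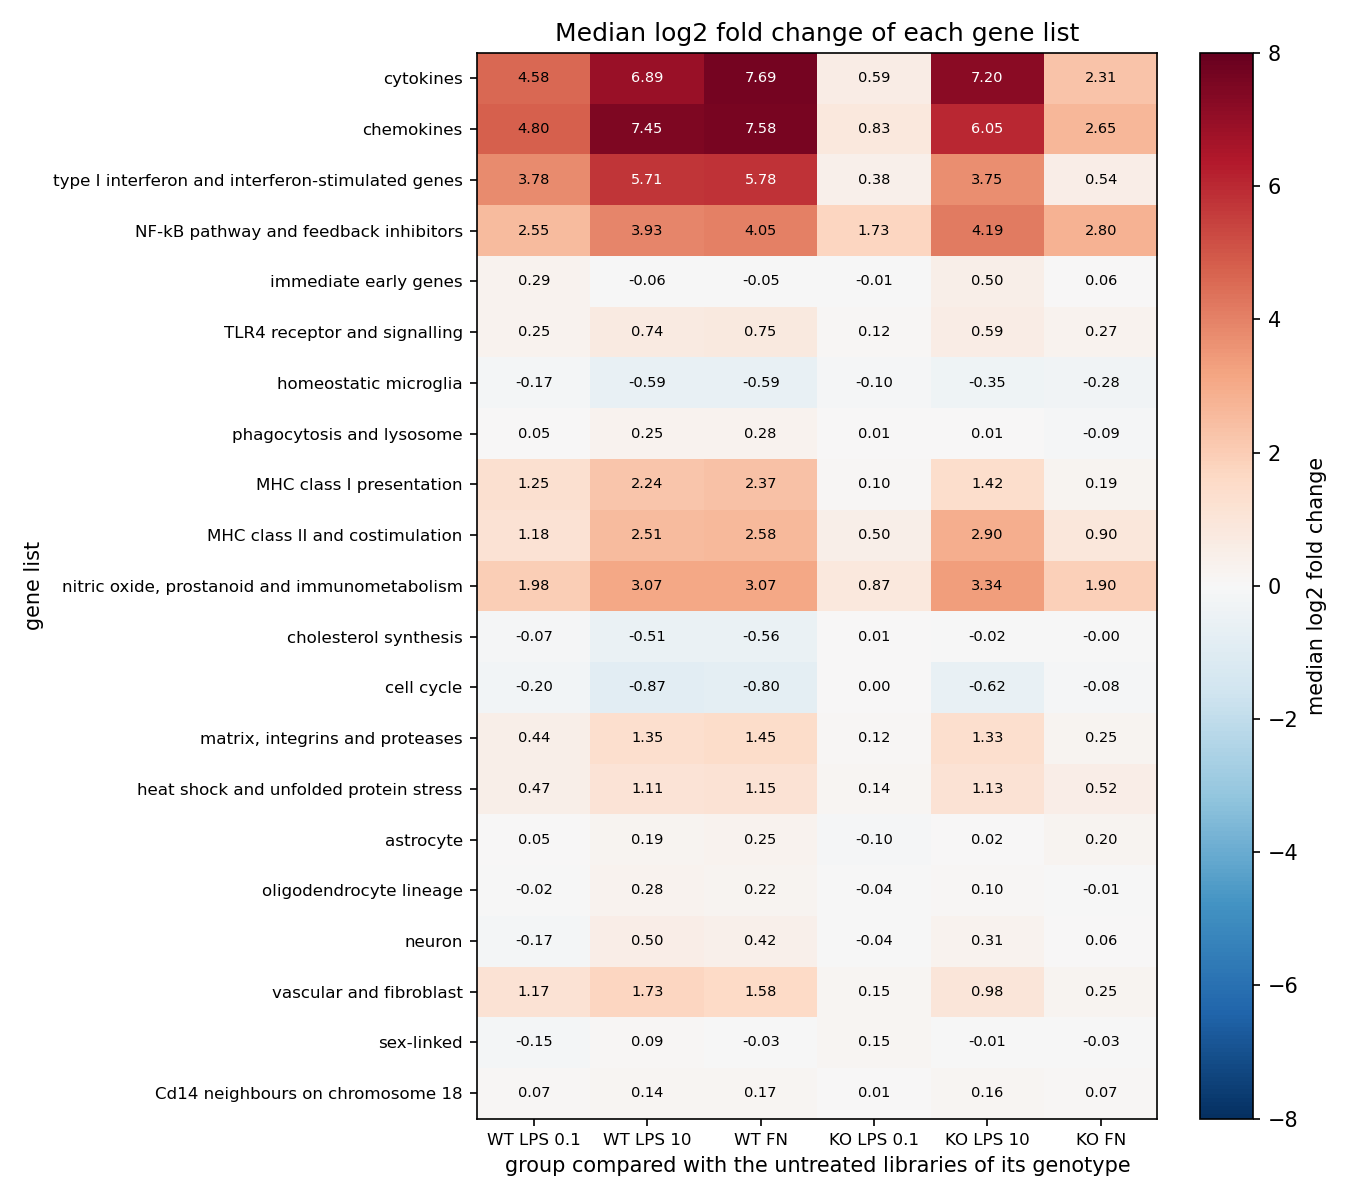
Median log2 fold change of 21 gene lists (rows) in each stimulated group against the untreated libraries of its genotype (columns; red higher, blue lower); genes with no count in a group were set to the bound that 3 counts allow. The interferon-stimulated list has medians of 3.78, 5.71 and 5.78 in wild-type cells and 0.38, 3.75 and 0.54 in CD14-deficient cells.

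Further lists were tested. Of 24 genes of the TLR4 receptor and its signalling, 15 rose and 1 fell in WT cells at LPS 10 ng/ml (15 and 1 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.198 with an estimated correlation), with Tlr2 at 3.84 ± 0.32 and the adaptor gene Myd88, which shares 11.3% of its exon length with another gene and is uncertain for that, at 3.05 ± 0.20. Of 10 MHC class II and costimulation genes 7 rose (8 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.0677 with an estimated correlation), with the checkpoint ligand gene Cd274 at 5.86 ± 0.35. Immediate early genes rose in 6 and fell in 4 of 18 (7 and 4 adjusted over the list alone), with a median of -0.06, a mean of 0.22 and an upward camera test (adjusted p = 0.328), with Junb at 3.37 ± 0.27. Phagocytosis and lysosome genes rose in 6 of 26 (5 adjusted over the list alone; camera adjusted p = 0.204). Between genotypes at LPS 10 ng/ml that list was lower in KO cells in 4 of 26 (4 adjusted over the list alone; camera adjusted p = 0.00100, and adjusted p = 0.0325 with an estimated correlation), with the phagocytic receptor gene Mertk at -2.88 ± 0.26. Matrix, integrin and protease genes rose in 10 and fell in 4 of 22 (10 and 4 adjusted over the list alone; camera adjusted p = 0.00830, and adjusted p = 0.237 with an estimated correlation), with the collagenase gene Mmp13 at 8.37 ± 0.54. Cholesterol synthesis genes fell in 6 and rose in 2 of 18 (6 and 2 adjusted over the list alone; camera adjusted p = 0.259), with Lss, which forms lanosterol, at -1.52 ± 0.23. Cell cycle genes fell in 2 of 22 (0 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 0.329, and 3.1e-04 with the nested block). Heat shock and unfolded protein genes rose in 6 of 16 (6 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.497 with an estimated correlation), with the chaperone gene Hspa5 at 1.94 ± 0.15.

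Markers of other cells were followed at LPS 10 ng/ml in WT cells. Of 12 astrocyte genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.741), the gap junction gene Gja1 (4.63 ± 0.88). Oligodendrocyte lineage genes rose in 1 and fell in 1 of 12 (1 and 1 adjusted over the list alone; camera adjusted p = 0.944). Of 11 neuronal genes 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.965). Vascular and fibroblast genes rose in 4 of 6 (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.132), with the mural cell receptor gene Pdgfrb at 6.14 ± 0.75 in WT and 7.01 ± 0.78 in KO cells at this dose. Of 16 genes of other leukocytes 1 was tested, Ccr2 (-1.59 ± 1.34, uncalled, and adjusted p = 1.7e-05 with the nested block), and none of 13 mitochondrially encoded genes was in the count table. Sex-linked genes gave 0 calls of 5 (median 0.09, downward camera test, adjusted p = 0.966), and the neighbours of Cd14 rose in 13 and fell in 6 of 42 (13 and 6 adjusted over the list alone; camera adjusted p = 0.308).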

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

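The tests of the WT LPS 0.1 ng/ml replicate 3 library below and the comparison of interferon-stimulated genes by library were chosen after the result was seen; the others were not. The replaced first test of Rn45s, leaving it out of the counts, had left that library's response at 0.678 and decided nothing.

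The responses of the genotypes differed by the interaction test, which singled out 305 genes at LPS 0.1 ng/ml, 702 at LPS 10 ng/ml and 3069 with FN. Among the genes named for every contrast, the interaction at LPS 0.1 ng/ml was negative for Ifnb1 (-7.13 ± 1.39, resting on 3 counts in untreated WT cells), Cxcl10 (-6.28 ± 0.79), Il6 (-5.38 ± 0.98), Il12b (-5.12 ± 0.87), Ccl5 (-4.39 ± 0.81) and Tnf (-2.65 ± 0.61). With LPS 10 ng/ml it was negative for Ifnb1 (-5.65 ± 1.29). With FN it was negative for Ifnb1 (-10.41 ± 1.35), Il6 (-8.83 ± 0.98), Cxcl10 (-6.63 ± 0.80), Il12b (-6.33 ± 0.88), Ccl5 (-4.76 ± 0.81), Tnf (-2.36 ± 0.61) and Cd14 itself (-2.26 ± 0.69), which KO cells cannot raise. With single libraries left out, each named with its value in the results, the Tnf call at LPS 0.1 ng/ml ended (adjusted p up to 0.101) and so did the Cd14 call with FN (up to 0.0603). Of the lists, interferon-stimulated genes (median -3.58), chemokines (-2.98), cytokines (-2.65, the same with genes at 0 set to their bound) and NF-kB genes (-1.19) had weaker responses in KO cells at LPS 0.1 ng/ml with the preset and with the estimated correlation. With FN this held for interferon-stimulated genes (-5.31), cytokines (-4.16, or -3.99 with genes at 0 set to their bound) and MHC class I presentation (-1.95).

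Exchanging libraries between the genotypes at random gave as many genes in 8 of 100 splits for each interaction, the real one included. The highest counts of other splits were 534 at LPS 0.1 ng/ml, 916 at LPS 10 ng/ml and 3633 with FN. In each case the 7 other splits with as many kept the treated libraries with their genotype and exchanged untreated libraries alone, so that they hold the treated difference itself and the count does not decide on chance. The highest count among the 92 splits that mixed treated libraries was 0, but 6 treated libraries have 10 splits, too few for a share under 0.05.

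WT cells gave the same response to FN as to LPS 10 ng/ml within the error, with 0 genes called. Low precision is argued against for most of the genes called at LPS 10 ng/ml. Of these, 90.35% had a 95% interval of the difference within 2-fold with the nested replicate block, and 81.98% without it. Picking genes by that call favours small errors and reuses the LPS 10 ng/ml libraries. Without the block, the errors of Il12b, Cxcl10, Cxcl1 and Ifnb1 given in the results leave a difference over 2-fold possible. A shared direction of response was tested in KO cells, where the stimuli are apart: of the genes called with FN, 4.92% went beyond LPS 10 ng/ml in the same direction, beside 5.24% for WT cells at LPS 0.1 ng/ml. These shares count only called genes and cannot show genes that fail to respond. The responses differed by list: most interferon-stimulated genes rose in WT cells at LPS 0.1 ng/ml, and few in KO cells with FN. Genotype and stimulus both differ there. In KO cells LPS 0.1 ng/ml left these genes uncalled, so the comparison does not separate FN from LPS. Whether FN acts along the LPS response in KO cells stays open: 4.92% lies between the bounds set for either answer. Those bounds cannot decide it. A lower LPS dose alone, at 5.24% in WT cells, lies above the upper bound. Bacterial LPS carried in the FN, a shared receptor for FN and LPS, and an effect of FN on its own cannot be told apart here, since the series has no FN freed of LPS.

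Interferon-stimulated genes lost more of the LPS 10 ng/ml response without CD14 than NF-kB genes, with median interactions of -1.90 and -0.13. A larger loss in genes with a larger WT rise, whatever their pathway, is argued against if genes are taken as independent: 0.04% of 10000 random lists matched on the WT change had a median as low, their middle value being -0.96 and their lowest -1.96, and the NF-kB list lay at the percentile 99.46 of lists matched on its own WT change, with a middle value of -0.77, so that NF-kB genes losing less than others is part of the gap. Interferon-stimulated genes move together, however, and the response of the list in excess of matched genes, library by library, was 0.07, -0.57 and -0.61 in KO and 0.92, 0.25 and 0.21 in WT cells, a difference of -0.83 with a 95% interval from -1.72 to 0.0512, so that spread between preparations cannot be excluded; within numbers the difference was -0.86, -0.83 and -0.82, but at LPS 10 ng/ml libraries of number 3 correlated between the genotypes at 0.0936, too weakly to pair. A single KO library is argued against as the whole cause, since the difference between the lists was -1.77 with all libraries and -1.36 in the smallest of the fits without 1 of the KO LPS 10 ng/ml libraries, that without replicate 3. A pathway to interferon that depends more on CD14 than the pathway to NF-kB may explain this but stays open, with 9 of 36 interferon-stimulated genes called and a camera adjusted p of 0.0677 with an estimated correlation, and genes near saturation in both genotypes were not tested.

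The WT LPS 0.1 ng/ml replicate 3 library had a smaller response than the other 2, a median of 0.678 over 1820 genes raised in WT cells at LPS 10 ng/ml, against 1.11 and 1.04. An untreated culture under this label is argued against by that same value, set against the untreated library of its number. Whether its share of Rn45s lowers the response cannot be told: the other 2 libraries rich in Rn45s had the highest response of their groups, but by 0.113 and 0.0598, less than the 0.169 and 0.0666 by which the libraries beside them differed. Untreated Cd14 levels of 1150, 639 and 338 CPM rank as the responses do, but 3 numbers give an exact p of 0.167, the smallest possible, so whether less Cd14 could lower the response cannot be told. A weaker dose in that culture was not tested.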

How the results depend on the processing

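The 2 settings on Rn45s were chosen after seeing the data; the other alternatives were not. Of the 17 counts of called genes, all stayed within 1.5 times their value with RLE scaling, without a filter, with the stricter filter, with limma on the normalized values and with Rn45s left out; the fits below moved some of them, and the cause was not tested except where the construction gives it. No called value of a named gene or list changed direction under any alternative. Whether more genes rose or fell did change with DESeq2 and with RLE scaling for WT LPS 10 ng/ml (3529 up and 3310 down, 3382 and 3231), WT FN (3519 and 3395, 3382 and 3285), KO LPS 10 ng/ml (3124 and 2857, 2985 and 2696), KO against WT at LPS 10 ng/ml (1113 and 1256, 968 and 1076), the FN interaction (1592 and 1834, 1381 and 1635) and the doses in WT (2411 and 2129, 2232 and 2027) and KO cells (2785 and 2428, 2616 and 2262). It changed too with the nested replicate block for KO FN (2860 up and 2991 down) and the interaction at LPS 10 ng/ml (1507 and 1380), with limma for KO against WT at LPS 10 ng/ml (1065 and 1137) and the FN interaction (1562 and 1594), with the stricter filter for the doses in KO cells (2352 and 2328), and with the compared groups alone for KO LPS 10 ng/ml (2248 and 1785), KO against WT at LPS 10 ng/ml (198 and 447) and the doses in KO cells (1780 and 1408). Single libraries left out changed it as well for KO LPS 10 ng/ml (without KO untreated replicate 3, 2848 up and 2629 down, and KO LPS 10 ng/ml replicate 1, 2567 and 2475, or 2, 2795 and 2651), KO against WT at LPS 10 ng/ml (without WT LPS 10 ng/ml replicate 1, 752 and 866, or 2, 726 and 893, and KO LPS 10 ng/ml replicate 3, 572 and 728), the FN interaction (without WT untreated replicate 1, 1316 and 1363, or 3, 1292 and 1331, WT FN replicate 2, 1413 and 1488, KO untreated replicate 1, 1336 and 1405, or 2, 1313 and 1420, and KO FN replicate 3, 1364 and 1425) and the doses in KO cells (without KO LPS 0.1 ng/ml replicate 3, 2387 and 2146, and KO LPS 10 ng/ml replicate 1, 2135 and 2036, or 2, 2430 and 2213). With the replicate number as a block, counts rose to 3152 (WT LPS 0.1 ng/ml), 190 (KO LPS 0.1 ng/ml), 3431 (KO FN), 19 (KO against WT untreated), 2507 (KO against WT, LPS 0.1 ng/ml), 3337 (KO against WT, LPS 10 ng/ml, where number 3 correlated at only 0.0936, so that the numbers do not all pair), 564 and 1280 (interactions at LPS 0.1 and 10 ng/ml) and 3539 (KO FN against LPS 10 ng/ml). With the nested replicate block they rose to 5520 (WT LPS 0.1 ng/ml), 515, 8778 and 5851 (KO LPS 0.1 ng/ml, LPS 10 ng/ml and FN), 1779, 2887 and 6553 (interactions at LPS 0.1 ng/ml, LPS 10 ng/ml and FN), 7576 and 8346 (doses in WT and KO) and 5952 (KO FN against LPS 10 ng/ml); either block takes out the deviation that libraries of 1 number share. Fits of the compared groups alone, which have fewer libraries to estimate the spread, gave 1357 (WT LPS 0.1 ng/ml), 45 (KO LPS 0.1 ng/ml), 1246 (KO FN), 0 (KO against WT untreated, where edgeR had 130 genes at an unadjusted p under 0.05 over all libraries and DESeq2 called 2 and limma 1), 179 and 645 (KO against WT at LPS 0.1 and 10 ng/ml), 432 (interaction at LPS 10 ng/ml), 3188 (doses in KO) and 879 (KO FN against LPS 10 ng/ml). DESeq2 gave 186 (KO LPS 0.1 ng/ml), 2 (KO against WT untreated) and 588 (interaction at LPS 0.1 ng/ml). Without the 3 libraries rich in Rn45s, 483 genes had an interaction at LPS 0.1 ng/ml and 2419 differed between doses in WT cells.

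Leaving out 1 library at a time gave, as lowest and highest counts, 1317 and 2546 (WT LPS 0.1 ng/ml), 5870 and 6193 (WT LPS 10 ng/ml), 5930 and 6313 (WT FN), 55 and 98 (KO LPS 0.1 ng/ml), 4907 and 5477 (KO LPS 10 ng/ml), 1564 and 2013 (KO FN), 1 and 1, 604 and 1934, 1300 and 2210, and 4377 and 4716 (KO against WT untreated, LPS 0.1 ng/ml, LPS 10 ng/ml and FN), 180 and 624, 445 and 840, and 2623 and 2901 (interactions at LPS 0.1 ng/ml, LPS 10 ng/ml and FN), 2944 and 4000, and 4152 and 4643 (doses in WT and KO), 0 and 0 (WT FN against LPS 10 ng/ml) and 1490 and 1958 (KO FN against LPS 10 ng/ml). Genes picked at the same WT stimulus, which favours WT through the treated libraries too, gave induced medians of 2.06 in WT and 0.53 in KO cells at LPS 0.1 ng/ml. They were 2.09 and 1.61 at LPS 10 ng/ml and 2.07 and 0.61 with FN. RLE scaling gave 0.19 in KO cells at LPS 0.1 ng/ml. With calls of at least 2-fold, FN and LPS 10 ng/ml shared 3606 genes in WT and 881 in KO cells.

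Of the 220 values of named genes, the compared groups alone ended the call in 17 and made 1, no filter ended 3, limma ended 1 and made 2, DESeq2 made 5, and the replicate number as a block made 7; these included the interactions of Cd14 and Cxcl10 at LPS 10 ng/ml, called by DESeq2 too (adjusted p = 0.0173 and 0.0211), and Cxcl1 (0.0123) and Ccl5 (0.0301) between genotypes at LPS 10 ng/ml with the replicate number as a block. The estimated correlation ended 28 camera calls among the 76 list results named, and the blocks changed 3; apart from the calls named here and beside their results, a block changed no other call. Depth limits genes near 0, such as Ifnb1 in untreated cells.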

Other observations

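The genes called between untreated genotypes with the replicate number as a block were chosen after their values were seen. The test of the segment around Cd14 was not, but the neighbours of Cd14 on chromosome 18 had been seen as a list, without a shift, before it was written.

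Mertk, the receptor with which macrophages engulf dying cells, fell in KO cells at LPS 10 ng/ml and with FN and did not fall in WT cells there. In WT cells it stood at 138 ± 19.3 CPM untreated, 61.2 ± 14.3 at LPS 0.1 ng/ml (log2 fold change -1.18 ± 0.24, adjusted p = 0.00193), 227 ± 50.3 at LPS 10 ng/ml (0.71 ± 0.24, adjusted p = 0.0177) and 209 ± 22.5 with FN (0.59 ± 0.24, adjusted p = 0.0459). The last 2 calls ended without single libraries (adjusted p up to 0.107 and 0.154), and the FN call also without a filter (0.0639), with the stricter filter (0.0539) and without the 3 libraries rich in Rn45s (0.0675). In KO cells it stood at 143 ± 30.2, 97.9 ± 27.5, 30.9 ± 9.70 (-2.22 ± 0.25, adjusted p = 9.9e-07) and 25.7 ± 2.37 CPM (-2.48 ± 0.25, adjusted p = 1.5e-06). The interaction was -2.93 ± 0.34 at LPS 10 ng/ml (adjusted p = 9.1e-05) and -3.07 ± 0.34 with FN (adjusted p = 4.5e-06). Irf8 took opposite courses with FN, from 311 ± 20.6 to 2003 ± 320 CPM in WT cells and from 336 ± 8.41 to 189 ± 15.7 in KO cells. At LPS 0.1 ng/ml the means of both genes were below untreated in both genotypes, with Irf8 at 244 ± 25.4 CPM in WT and 258 ± 21.96 in KO cells. Pdgfrb, a receptor of mural cells and fibroblasts, went from 0.236 ± 0.164 to 15.3 ± 6.95 CPM with FN in WT cells (5.99 ± 0.74, adjusted p = 1.9e-06) and from 0.165 ± 0.120 to 1.94 ± 0.95 in KO cells (3.44 ± 0.71, adjusted p = 0.00213).

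Between untreated genotypes, the genes called with the replicate number as a block were mostly lower in KO cells. Folr2, a folate receptor of tissue macrophages, stood at 56.4 ± 15.1 CPM in WT and 32.5 ± 6.38 in KO cells (log2 fold change -0.78 ± 0.08, adjusted p = 1.3e-04), lower in KO cells in 3 of 3 untreated pairs of a number, which the choice of genes by that fit favours. The same held for Rab6b, a trafficking GTPase (-1.63 ± 0.13, adjusted p = 1.6e-06), Fabp7, a fatty acid carrier (-1.53 ± 0.27, adjusted p = 0.0259) and Tril, a TLR4 accessory protein (-2.29 ± 0.42, adjusted p = 0.0387). Tril was near 0 in both, at 2.12 ± 2.28 CPM in WT and 0.388 ± 0.36 CPM in KO cells, so its value is uncertain. The lectin receptor gene Clec4a1 (-1.24 ± 0.20, adjusted p = 0.0140) was lower in 3 of 3 untreated pairs too, and the synaptic Clstn1 (0.84 ± 0.11, adjusted p = 0.00288) was higher in KO cells in 3 of 3. Across genotypes the pairing of numbers is weak, with WT number 3 correlating at 0.557 to 0.713 with KO number 2.

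A segment around the altered Cd14 gene that stems from the strain in whose cells the allele was made may account for differences near Cd14, but the genes above lie outside it. Within 10 Mb of Cd14, 11 of 128 genes (8.59%) had an unadjusted p under 0.05 between untreated genotypes with the replicate number as a block, against 456 of 11776 elsewhere (3.87%; Fisher's exact p = 0.0177). That block rests on the weak pairing of numbers between genotypes, and Fisher's test takes neighbouring genes as independent, so this p-value is uncertain. None of the 11, among them Bin1 (-0.41 ± 0.09) and Ythdc2 (-0.44 ± 0.12), passed adjustment, and none is among the genes called with the block. Other differences between the mouse colonies were not tested, and a marker of strain in the reads was not available.

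Other splits of the libraries were counted for each contrast of 3 against 3. There are 10 such splits, too few for a share under 0.05. The real split gave the most calls, 1 of 10 with as many, for WT LPS 0.1 ng/ml (2075), WT LPS 10 ng/ml (6570), WT FN (6670), KO LPS 0.1 ng/ml (97), KO LPS 10 ng/ml (5697), KO FN (2180), KO against WT untreated (1), at LPS 0.1 ng/ml (1237), at LPS 10 ng/ml (2114) and with FN (5130), the doses in WT (4285) and KO (4883) and FN against LPS 10 ng/ml in KO cells (2258), with 0 as the highest of the other splits in each. For FN against LPS 10 ng/ml in WT cells the real split called 0 and the highest other 2, so that 10 of 10 had as many. The genes shared by FN and LPS 10 ng/ml exceed the number for independent lists (735 up and 919 down in WT cells). Part of the excess may come from the shared untreated libraries. Simulated unchanged groups shared 0 genes, but they cannot show how much those libraries add where many genes change. With calls of at least 2-fold, 3606 genes were shared in WT cells.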
